A study of Caenorhabditis elegans with 66 samples.

How the data were processed

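Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in the nematode Caenorhabditis elegans on 3 FLAG-tagged subunits of the small nuclear RNA activating protein complex (SNAPc), namely SNPC-4 and the related SNPC-1.1 and SNPC-1.2. The series holds 66 samples, made of 33 immunoprecipitated (IP) libraries and an input library for each. The IP libraries form 11 groups of 3 replicates, of which 7 are tagged strains and 4 are the untagged wild type N2. They fall into 3 datasets. Dataset 1 covers SNPC-1.2 in whole worms at 72 h (gravid adults), dataset 2 covers SNPC-4 in whole worms at 48 h (the last larval stage, L4) and 72 h, and dataset 3 covers SNPC-1.1 in germline nuclei at 56 h (young adults).

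Per the labels, worms grew in liquid culture at 20 °C and chromatin was cross-linked with formaldehyde. Sequencing was paired-end with 50-bp reads. For staged collections part of a culture was harvested at 48 h and the remainder was grown on, so libraries of both ages may come from shared cultures. The labels do not tie replicate numbers to cultures. The descriptions of N2 replicate 2 in dataset 3 name SNPC-1.2 where those of the other libraries of that dataset name SNPC-1.1, and it was used as N2 of dataset 3, as its title says.

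The submitters' notes name MACS2 2.1.2 as the peak caller, deepTools without a version, and the genome build WBcel235. They state neither an aligner nor filters. Each IP library has 1 deposited peak list, called against its own input. In column 7 the deposited lists give a ratio, the fold of IP signal over input at the summit as the authors computed it. In column 9 the deposited lists give the −log10 of the q value at the summit. The summit position, a deposited offset in bp from the region start of another kind than a signal value, was used to place each peak. The lowest −log10 q in any list lies near 1.30, which corresponds to q = 0.05. The authors' caller split broad regions into several summits that repeat the whole region's start and end. Removing a region therefore removes every summit inside it.

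No reads or read counts were used, so the depth of each library is unknown, and no counting interval or lower limit is given. The number of peaks in a list is not a depth. Authors' folds and q values were used only to rank, filter or describe peaks within a list, and never compared between libraries in a test. Over all 528 pairs of lists, the share of the shorter list's summits found at the same base in the other was at most 12.5%, or at most 2.85% where both lists held over 100 peaks.

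A gene of up to 500 bp was counted as having a peak when a summit lay within 200 bp of its annotated span. A longer gene was counted when a summit lay within 200 bp of either end. The design had named the 5′ end, which was replaced because the annotation used here gives no strand. Gene lists came from biotypes or names among 46926 annotated genes. They were 15363 piRNA genes, 98 snRNA genes, 10 SmY RNA genes, 12 SL1 and 18 SL2 spliced leader RNA genes, 634 tRNA genes, 346 snoRNA genes, 260 miRNA genes, 22 rRNA genes, 3 other genes of RNA polymerase III (rpr-1, mrpr-1 and yrn-1), 72 histone genes, 78 ribosomal protein genes and 19983 protein-coding genes. The SmY genes are also part of the snRNA list. The piRNA clusters were taken as chromosome IV from 4500000 to 7000000 bp (the smaller) and from 13500000 to 17200000 bp (the larger). Reads from near-identical copies of SL1, tRNA and 5S rRNA genes may be lost or shared in mapping, so values for these lists describe listed peaks only.

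The values compared were the percent of a list's genes with a peak and the percent of a library's peaks inside the clusters. Every summit of a split region counts as a peak in the latter share. Groups of 3 against 3 were compared by exact two-sided permutation tests over all 20 labellings, whose smallest p is 0.1. Tests stratified over 2 ages had 400 labellings (smallest p 0.005), and those over the 4 tagged-N2 pairs had 160000 (smallest p 1.25e-05). Benjamini-Hochberg adjustment was made over 30 main tests and, separately, over 252 tests of other gene lists. Several comparisons share the same libraries, so their chance values are shared. The p-values measure only the spread between samples. Genes were also counted as gained or lost when all 3 libraries of one group and none of the other had a peak. Leaving out a library relaxes this rule, so such counts can then only stay or rise. When a gene has a peak in exactly 3 of the 6 libraries, chance puts all 3 in one group in 10% of arrangements. No gene-level p was called. For piRNA genes the counts were repeated over all 10 splits of the 6 libraries. In replicate blocks a gene counted when at least 2 of the 3 same-numbered pairs changed and none changed the other way. This looser rule takes in every gene of the main count.

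Consensus regions were those called in at least 2 of 3 libraries of a group, merged at 1 bp of overlap, without those that overlapped a peak of an N2 library of the same dataset and age. Overlaps of consensus regions were compared with 1000 circular shifts within chromosomes by a one-sided permutation test with smallest p 0.001. These shifts test position and say nothing about replicate error. Chromosome lengths for the shifts were the last base any peak reached.

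Genes named were picked by a rule fixed before the data were examined, as were the comparisons, gene lists and permutation tests, while the positional excess, the division into larger and smaller cluster and several tests of explanations were chosen later. For each comparison and direction it takes genes gained or lost in all libraries, up to 6 piRNA genes and up to 4 of each other list, ordered by the median authors' fold, ties by position. Where a list has no such gene, it takes the 2 members with a peak in most libraries of the first group. It adds 13 loci of SNAPc and piRNA factors and the 5 best-ranked consensus regions of each tagged group.

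Replicate numbers were checked for pairing by correlating deviations from group means between same-numbered libraries. Every pair exceeded 0.1 for SNPC-1.2 against N2 (0.127 to 0.251), for the SNPC-4 AID strain against SNPC-1.2 (0.307 to 0.592) and for snpc-1.3(-) against its control (0.462 to 0.847). A blocked count stands beside the last 2 of these. The counting rule was tested on simulated data with 15363 genes of which 200 changed: it recovered 200, and called 3 of 15163 unchanged genes. The changed genes were set without noise, so their recovery was fixed in advance. Noise was drawn for each gene alone, while in real lists neighbouring genes share summits. The 3 calls therefore understate the error, as other splits of the real libraries gave up to 62 piRNA genes. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

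Alternatives tried were windows of 100 and 500 bp, any overlap of a region, a −log10 q of at least 10, a fold of at least 3, lists shortened to the shortest list of the comparison, removal of N2 peaks, cluster genes only, replicate blocks, leaving out each library, stricter consensus rules, and 3 added after the data were seen. Upstream motif tests of piRNA genes and the division of snRNA genes by class need a genome sequence and were not run. Input libraries were used only through the authors' peak calls.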

Results

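Peak lists from 33 IP libraries were compared, in 11 groups of 3 replicates (whole worms, except germline nuclei for SNPC-1.1 and its N2). In dataset 1, the lists held 9926, 8397 and 4791 peaks for SNPC-1.2 at 72 h, 281, 81 and 67 for SNPC-1.2 in the SNPC-4 AID strain, and 16, 2 and 2 for N2. In dataset 2 at 48 h they held 15078 to 16323 peaks for SNPC-4, 15933 to 16732 for SNPC-4 in worms without snpc-1.3, and 947 to 2930 for N2. At 72 h they held 15682 to 16534 for SNPC-4, 14538 to 16451 for SNPC-4 in worms without snpc-1.2, and 1400 to 4229 for N2. In dataset 3 at 56 h, replicates 2, 3 and 4 held 14912, 1504 and 10238 peaks for SNPC-1.1 and 764, 1001 and 28 for N2, of which replicate 2 has a description that names SNPC-1.2. The read depth behind these lists is unknown. Values below are mean ± SD with n = 3 libraries unless stated, and coordinates are on WBcel235.

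The first question was which genes each tagged SNAPc subunit occupied compared with untagged worms. SNAPc is the complex that starts transcription of small nuclear RNA genes, and piRNA genes of the worm are short germline RNA genes packed mostly into a pair of clusters on chromosome IV. SNPC-1.2 peaks at 72 h lay at 59.4% ± 9.03 of 15363 piRNA genes, against 0% in N2. SNPC-4 peaks lay at 61.7% ± 1.55 at 48 h, against 0.117% ± 0.0854 in N2, and at 63.4% ± 1.22 at 72 h, against 0.195% ± 0.108. After moving all summits by 2 to 5 kb, cluster piRNA genes still had a peak at 50.2% for SNPC-1.2 (63.4% ± 9.53 unmoved) and at 53.9% and 54.6% for SNPC-4 at 48 h and 72 h (65.5% ± 1.62 and 67.5% ± 1.29 unmoved). SNPC-1.1 peaks in germline nuclei lay at 3.28% ± 2.16, against 0.0412% ± 0.0370. For snRNA genes, which encode the RNAs of the splicing machinery and their relatives, the order differed. SNPC-1.1 had a peak at 74.1% ± 8.56 of 98 snRNA genes (N2 8.50% ± 6.56), SNPC-4 at 77.9% ± 0.589 and 81.0% ± 1.18 (N2 19.7% ± 4.82 and 21.1% ± 3.58), and SNPC-1.2 at 36.7% ± 13.8 (N2 0%).

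Over the 4 tagged-N2 pairs together, both lists were higher in tagged worms: piRNA genes at 46.9% against 0.0884% and snRNA genes at 67.4% against 12.3%, each with exact two-sided stratified permutation p = 1.25e-05, the smallest possible, and adjusted p = 0.000188 over 30 tests. For SNPC-4 over both ages the means were 62.6% against 0.156% for piRNA genes and 79.4% against 20.4% for snRNA genes, with exact permutation p = 0.005 and adjusted p = 0.0375 each. In each single pair all 3 tagged libraries lay above all 3 N2 libraries, with exact permutation p = 0.1, the smallest the design allows, and adjusted p = 0.136. Tagged lists held more peaks than the N2 lists of their pair, and longer lists alone place peaks at more genes. These tests therefore do not show a preference for piRNA or snRNA genes over others.

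**Figure D1:**
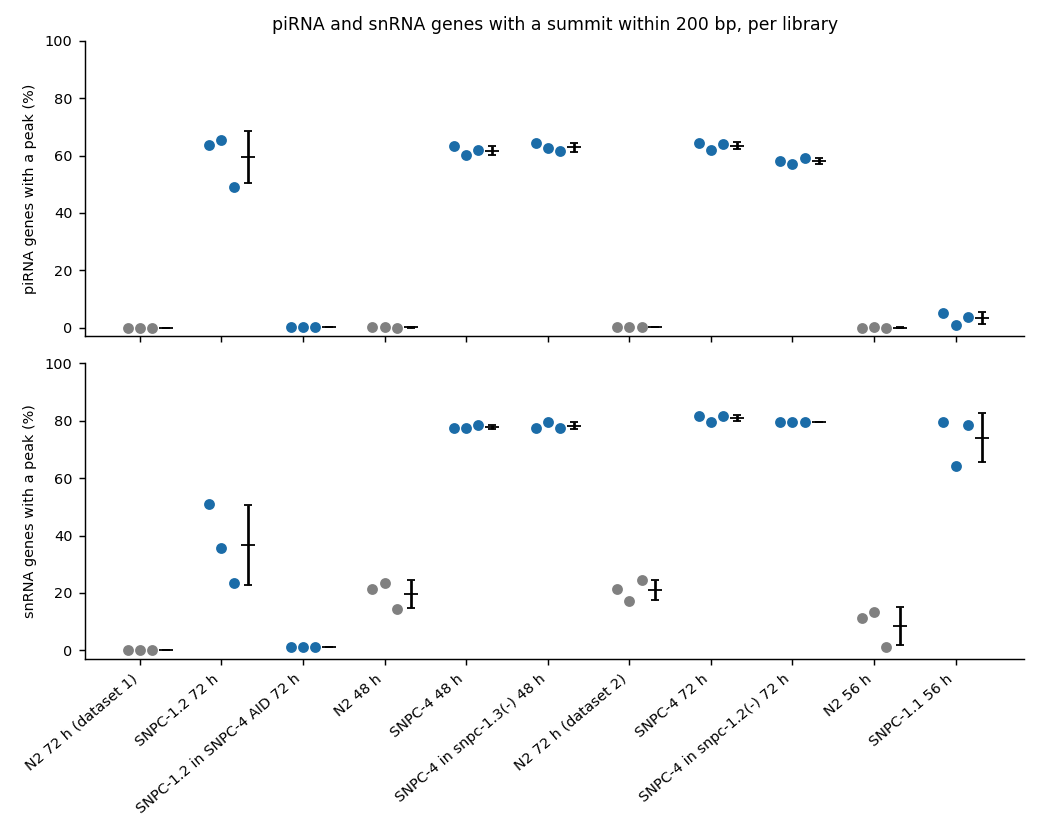
Percent of piRNA genes and of snRNA genes with a peak (y axes) in each IP library, by group (x axis), with points for libraries and mean ± SD for n = 3. SNPC-1.1 stands near 3.28% for piRNA genes and 74.1% for snRNA genes, while SNPC-4 at 72 h stands near 63.4% and 81.0%.

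SNPC-1.2 at 72 h was concentrated in the clusters, which held 78.5% ± 9.48 of its peaks, with every summit counted. Of its 2081 consensus regions, where the summits of a region count together, 29.5% lay in the clusters. In the larger cluster it had a peak at 68.9% ± 4.18 of 11388 piRNA genes, and elsewhere in the genome at 10.4% ± 2.98 of 1159. In the smaller cluster replicates 1 and 2 had a peak at 59.6% and 59.1% of 2816 piRNA genes, and replicate 3 at 4.15%. When the lists of replicates 1 and 2 were shortened by q value to the 4791 peaks of replicate 3, their values there were 2.31% and 10.2%, while the larger cluster kept 68.7% and 71.0%. All 3 libraries and no N2 library had a peak at 5047 piRNA genes, which became 7956 without SNPC-1.2 replicate 3. The 6 such piRNA genes with the highest fold, among them 21ur-5470 and 21ur-3160 (IV:14224943 to 14224988, fold 43.2) and 21ur-1058 (IV:15235235, fold 38.8), all lay within 500 bp of another short RNA gene, here the tRNA genes F02H6.t1 and Y73F8A.t1, so the fold cannot be assigned to the piRNA gene alone. Among other short RNAs, the snRNA gene Y57G11C.35 (IV:14764848 to 14765034) had fold 40.6, and smy-8, smy-10 and smy-9, genes of nematode SmY RNAs that take part in trans-splicing, had 14.8, 12.1 and 11.6. The SL2 spliced leader genes sls-2.17, sls-2.13 and sls-2.12 had 15.1, 13.2 and 12.6, the tRNA genes sup-24 and Y7A9D.t3 37.8 and 36.5, the snoRNA gene Y67A10A.14 51.3, and the microRNA gene mir-78 8.01. All of these lie in the clusters. Outside them, the histone gene his-68 had fold 6.36 and the ribosomal protein gene rpl-12 7.01. Protein-coding genes of the clusters with high folds included Y73F8A.14 (34.1) and tsr-2 (27.1).

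SNPC-4 covered both clusters more evenly. At 48 h it had a peak at 64.9% ± 1.94 of piRNA genes in the larger cluster and 67.7% ± 0.338 in the smaller, and at 72 h at 68.1% ± 1.32 and 65.1% ± 1.22. The piRNA genes with a peak in all 3 libraries and in no N2 library numbered 7861 at 48 h and 7892 at 72 h. The named ones, such as 21ur-15018 (fold 72.1 at 48 h), 21ur-3398 (50.0 at 48 h and 60.1 at 72 h) and 21ur-9767 (49.5 and 61.0), again all lay within 500 bp of another short RNA gene. All 10 SmY genes and 81.2% ± 1.07 of 634 tRNA genes had a peak at 48 h, and 100% and 82.8% ± 1.91 at 72 h, against N2 values of 0% and 30.2% ± 13.1 at 48 h and 6.67% ± 5.77 and 20.5% ± 11.1 at 72 h. For 18 SL2 genes the N2 background was high, 57.4% ± 14.0 at 48 h against 94.4% ± 0 for SNPC-4. For 12 SL1 genes, repeated copies on chromosome V, SNPC-4 had 11.1% ± 4.81 and N2 0%. Named snRNA genes included ZK897.4 (97.0), R07E5.16 (94.7) and F07C6.5 (91.2) at 48 h, and F07C6.5 (102) and F38E11.11 (90.2) at 72 h. Others were smy-1 (75.6) and sls-2.17 (85.1) at 48 h, sls-2.11 (58.5) at 72 h, the tRNA genes ZC412.t1 (78.4) at 48 h and Y37A1B.t1 (98.8) at 72 h, the snoRNA gene F47G4.9 (167) at 72 h, the microRNA genes mir-8196.1 (62.3) at 48 h and mir-2214 (57.9) at 72 h, the 5S rRNA gene rrn-4.12 (18.7 and 21.2), and yrn-1, a Y RNA gene (30.7 and 44.1). Protein-coding genes named were W01D2.3 (128) and msp-50 (59.1) at 48 h, and srw-63 (85.3) and nas-22 (61.1) at 72 h. The count of named genes near another short RNA gene was made only for piRNA genes. Folds of protein-coding genes, in any comparison, therefore cannot be assigned to those genes alone. In the other direction, 1 piRNA gene, 21ur-13200, had a peak in all N2 libraries and no SNPC-4 library at each age, with folds of 1.82 and 1.86, as did pck-1 (1.68 and 1.81), a gluconeogenic enzyme gene.

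SNPC-1.1 in germline nuclei lay at short RNA genes spread over the genome, with 8.73% ± 1.86 of its peaks in the clusters. Among snRNA genes with a peak in all 3 of its libraries and in no N2 library, the highest folds were at T08G5.11 (127), ZK897.2 (96.5) and ZK897.4 (84.8). The SL2 genes sls-2.16, sls-2.5 and sls-2.18, next to each other on chromosome III, had 116, 98.6 and 97.0. SNPC-1.1 also lay at rpr-1 (126) and mrpr-1 (67.9), the RNA components of RNase P and RNase MRP, and at yrn-1 (24.2) and smy-1 (60.6). Further genes were the tRNA gene C27A2.t1 (125), the snoRNA genes F25H2.15 (153) and W04D2.7 (141), and the microRNA gene mir-2214 (53.1). The homeobox gene ceh-8 had fold 134, but the region there also covered the non-coding RNA gene ZK265.11 and col-63. That fold therefore cannot be assigned to ceh-8 alone. Of 10 SmY genes 96.7% ± 5.77 had a peak, and of 18 SL2 genes 96.3% ± 3.21 (N2 0% and 22.2% ± 20.0). The count of piRNA genes with a peak in all 3 libraries and no N2 library was 72, and the 6 named, such as 21ur-3398 (56.2) and 21ur-5883 (45.9), lay within 500 bp of another short RNA gene. The short list of SNPC-1.1 replicate 3 limits such counts: without it they were 523 for piRNA genes (72 with it), 299 for tRNA genes (22 with it) and 81 for snoRNA genes (25 with it), while 49 snRNA genes had a peak in all 3 and in no N2 library with it included. After moving all summits by 2 to 5 kb the cluster piRNA genes with a SNPC-1.1 peak were 5.43%, above the 3.3% unmoved, and measured as the excess over moved summits the difference from N2 turned to −1.88 points (exact permutation p = 0.1, the smallest possible).

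**Figure D2:**
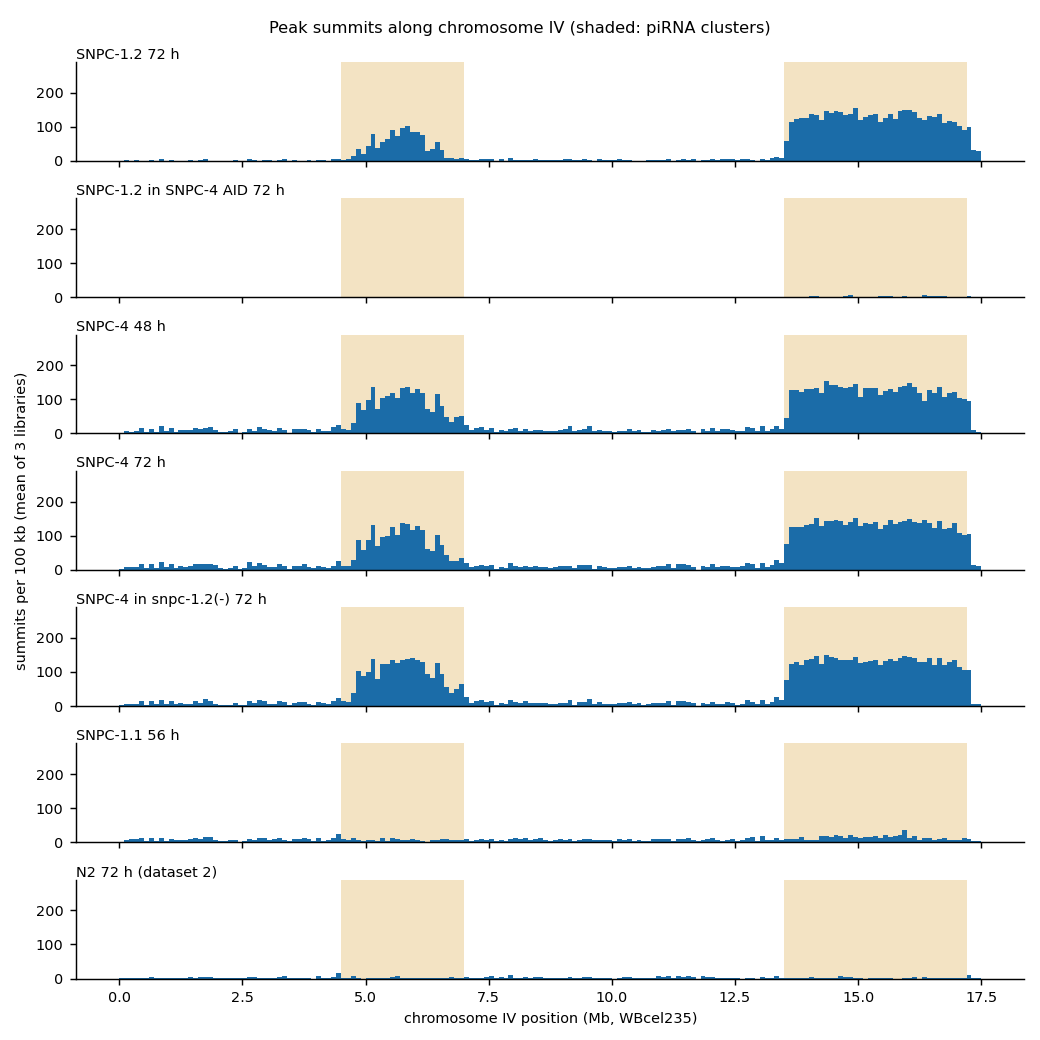
Summits per 100 kb (y axis) along chromosome IV (x axis) for 7 of the 11 IP groups, mean of 3 libraries, with the clusters shaded. The clusters hold 78.5% of all SNPC-1.2 peaks, 42.4% of SNPC-4 peaks at 72 h and 8.73% of SNPC-1.1 peaks.

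Across the other gene lists, the 4 tagged-N2 pairs gave higher percentages in tagged worms for SmY genes (89.2% against 1.67%, exact stratified permutation p = 1.25e-05, adjusted 0.000286 over 252 tests), tRNA genes (63.2% against 14.8%, exact p = 3.75e-05, adjusted 0.000630), ribosomal protein genes (32.1% against 8.23%, exact p = 0.000112, adjusted 0.00142) and all protein-coding genes (12.6% against 2.02%, exact p = 3.75e-05, adjusted 0.000630). The SNPC-1.1 libraries did not all lie above N2 for the last 3 lists, with 50.1% ± 38.8 of tRNA genes against 8.57% ± 9.20, 15.8% ± 13.8 of ribosomal protein genes against 3.85% ± 3.39 and 11.0% ± 8.97 of protein-coding genes against 0.929% ± 0.792 (exact two-sided permutation p = 0.3, 0.4 and 0.3, adjusted 0.409, 0.492 and 0.409). Tagged lists of these pairs held 1504 to 16534 peaks and N2 lists 2 to 4229. Longer lists alone place peaks at more genes of any kind, and neither equal lengths nor moved summits were compared for these lists. The p-values therefore do not show a preference for them.

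**Figure D3:**
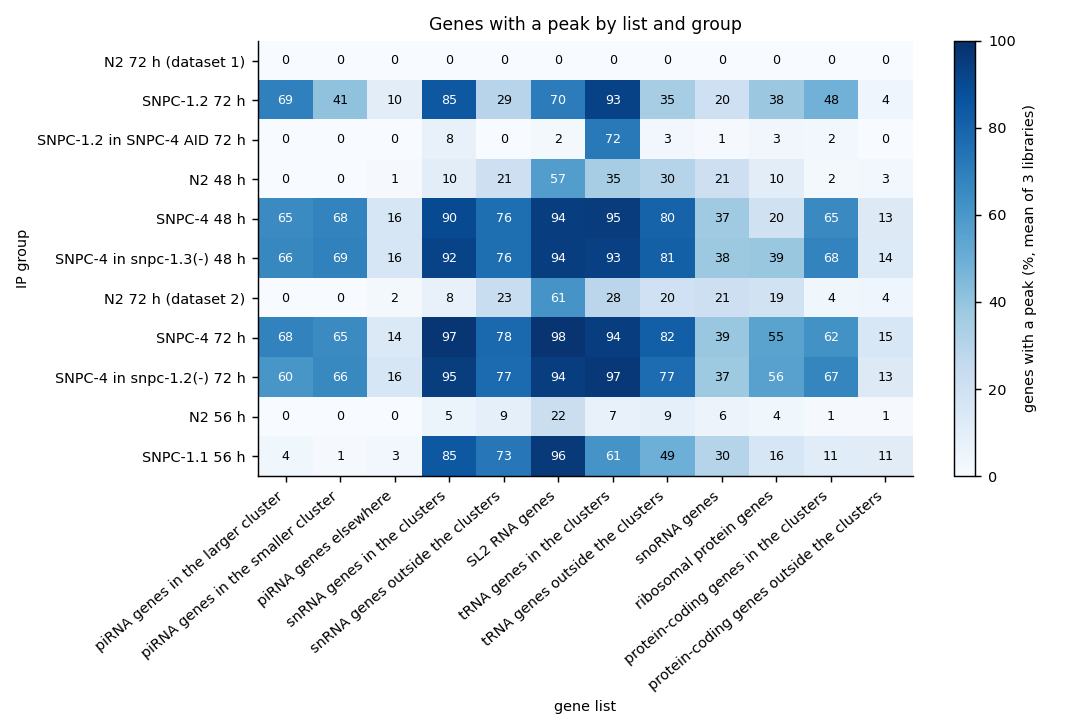
Mean percent of genes with a peak (colour) for 12 gene lists (columns) in the 11 IP groups (rows), n = 3 libraries each. In the SNPC-4 AID strain, tRNA genes stand at 71.5% in the clusters and at 2.53% outside them.

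The next question was whether SNPC-1.2 occupancy depended on SNPC-4. The AID strain carries SNPC-4 with an auxin-inducible degron and the TIR1 receptor under the germline sun-1 promoter, and the labels do not say whether auxin was given. SNPC-1.2 peaks lay at 0.122% ± 0.0554 of piRNA genes in this strain, against 59.4% ± 9.03 without the degron, and at 1.02% ± 0 of snRNA genes, against 36.7% ± 13.8. Of the piRNA genes, 5021 had a peak in all 3 SNPC-1.2 libraries and in no AID library, 0 showed the opposite, and 9 had a peak in all 6 libraries. Those lost included 21ur-15698 (IV:14526061 to 14526081, fold 26.9), and 5 of the 6 named lay within 500 bp of another short RNA gene. Also lost were smy-8 (14.8), sls-2.17 (15.1), the tRNA gene Y65A5A.t3 (14.4), mir-78 (8.01), the snoRNA gene T08B6.64 (13.4), the histone gene his-68 (6.36), the ribosomal protein gene rps-12 (4.00), and the protein-coding genes gtsf-1 (13.7), a small RNA pathway gene, rme-2 (10.6), the yolk receptor gene, and dpy-4 (8.38). The 1 snRNA gene with a peak in all 6 libraries was Y57G11C.35, with AID fold 3.43 against 40.6.

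Transfer RNA genes inside the clusters stood apart. In the AID strain 71.5% ± 12.0 of the 41 had a peak, against 92.7% ± 2.44 in SNPC-1.2, while outside the clusters 2.53% ± 2.34 of 593 had one, against 34.9% ± 22.8. Inside the clusters 24 tRNA genes had a peak in all 6 libraries, among them Y73F8A.t1 (AID fold 6.87, against 38.8) and Y7A9D.t3 (6.62, against 36.5). Of the 5 best-ranked AID consensus regions, all held a tRNA gene of the larger cluster (Y7A9D.t3, Y73F8A.t1, Y7A9D.t1, F02H6.t1 and F13G11.t1). The protein-coding genes Y73F8A.14 (5.77) and pqn-90 (5.50) also had a peak in all AID libraries. The share of peaks in the clusters was 55% ± 2.59 against 78.5% ± 9.48. With peaks of fold 3 or more the difference turned to 3.52 points (exact permutation p = 0.6). This share counts every summit of a split region. By consensus regions the order was the reverse, with 83.9% of 56 AID regions in the clusters against 29.5% of 2081 SNPC-1.2 regions. All 3 main differences, −59.2 points for piRNA genes, −35.7 for snRNA genes and −23.4 for the cluster share, had exact two-sided permutation p = 0.1, the smallest possible, and adjusted p = 0.136. The count of 5021 became 7929 without SNPC-1.2 replicate 3 and 9701 in replicate blocks, whose looser rules can only keep or raise it. It became 1 when every list was shortened to the 67 peaks of the shortest.

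The null strains asked whether SNPC-4 occupancy depended on the other SNAPc subunits. In worms without snpc-1.3 at 48 h, SNPC-4 had a peak at 62.9% ± 1.55 of piRNA genes, against 61.7% ± 1.55, and at 78.2% ± 1.18 of snRNA genes, against 77.9% ± 0.589. The share of peaks in the clusters was 43.1% ± 0.859, against 42.5% ± 0.393. None of these differences exceeded the replicate spread (exact two-sided permutation p = 0.5, 1 and 0.4, adjusted 0.556, 1 and 0.462), and the snRNA difference of 0.340 points turned to −0.340 without snpc-1.3(-) replicate 2. The cluster share difference of 0.615 points fell to 0.153 without snpc-1.3(-) replicate 1 and rose to 1.00 without its replicate 3. A peak in all libraries of both groups was found at 6881 piRNA genes, 75 snRNA genes and 483 tRNA genes, among them the snRNA gene C52E4.8 (null fold 212), sls-2.4 (230), rpr-1 (238) and the tRNA gene M01E5.t1 (176). Of the piRNA genes 63 were lost and 92 gained in all libraries, against up to 62 in the other splits of the same 6 libraries. Leaving out a library can only keep or raise these counts. For any of the 6 libraries they rose over 1.5 times, to 101 to 168 lost and 147 to 214 gained. Replicate blocks, with their looser rule, gave 472 and 612. Those gained included 21ur-11364 (7.88) and 21ur-3954 (7.21), those lost 21ur-5232 (7.88) and 21ur-8413 (7.82). The gained protein-coding genes included rpl-31 (1.92) and pmp-1 (3.14), and the lost ones tald-1 (2.45).

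In worms without snpc-1.2 at 72 h, SNPC-4 had a peak at 58.0% ± 0.989 of piRNA genes, against 63.4% ± 1.22, with all 3 null libraries below all 3 controls. Among piRNA genes the difference of −5.41 points lay in the larger cluster, with 60.3% ± 1.35 against 68.1% ± 1.32, and not in the smaller, with 65.8% ± 1.5 against 65.1% ± 1.22. Among piRNA genes 592 were lost and 248 gained in all libraries (395 gained without SNPC-4 replicate 3), against up to 56 in the other splits of the 6 libraries, and 548 of those lost lay in the larger cluster. The excess of losses turned with wider counting, to 65 lost and 84 gained at 500 bp and 7 lost and 80 gained by region overlap. Replicate blocks, with their looser rule, gave 1698 lost and 854 gained. The lost genes included 21ur-8500 (IV:16538064 to 16538084, fold 10.5), 21ur-6588 (9.48) and 21ur-11833 (9.04), and the gained ones 21ur-14204 (IV:13988370 to 13988390, fold 8.50) and 21ur-1516 (8.13). No named piRNA gene of the null comparisons lay within 500 bp of another short RNA gene. Other lost genes were the tRNA gene K02E2.t1 (2.88), the microRNA gene mir-58.2 (2.34) and dsh-2 (5.42), a Wnt signalling gene. Of protein-coding genes 125 were lost (191 without SNPC-4 replicate 2, 239 without null replicate 3) and 34 gained (57 without null replicate 1, 74 without null replicate 2), with 119 of the lost and 11 of the gained outside the clusters. Outside the clusters the lost were 181 without SNPC-4 replicate 2 and 230 without null replicate 3, and the gained were 20 without SNPC-4 replicate 1 and 26, 36 and 18 without null replicates 1, 2 and 3. The gained ones included C52D10.3 (7.54), irld-59 (7.03) and the collagen gene col-138 (6.76). No snRNA gene was lost or gained in all libraries, and 77 had a peak in all 6, among them sup-6 (null fold 223) and F38E11.10 (220), with 79.6% ± 0 against 81.0% ± 1.18. Cluster piRNA genes with a peak exceeded those with moved summits by 7.10 points ± 1.37 in the null and 12.8 ± 0.482 in the control. The share of peaks in the clusters was 46.9% ± 3.05, against 42.4% ± 0.678. This difference of 4.53 points fell to 2.77 without null replicate 1. Of consensus regions, which exclude those with an N2 peak and count a region's summits together, 10.6% and 11.4% lay there. The higher share in the null was therefore seen for summits only.

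Exact two-sided permutation p was 0.1, the smallest possible, for piRNA genes and the cluster share (adjusted 0.136) and 0.4 for snRNA genes (adjusted 0.462). The piRNA difference turned to 0.462 points when any region overlap counted and to 2.56 points when regions with N2 peaks were removed. Over both nulls together the cluster share differed by 2.57 points (exact permutation p = 0.02, adjusted 0.120), with p = 0.0625 in replicate blocks and 2.38 points at exact p = 0.06 without SNPC-4 72 h replicate 3. Without snpc-1.2(-) replicate 1 it was 1.7 points (exact permutation p = 0.02). The piRNA percentage over both nulls differed by −2.14 points (exact permutation p = 0.125, adjusted 0.163).

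**Figure D4:**
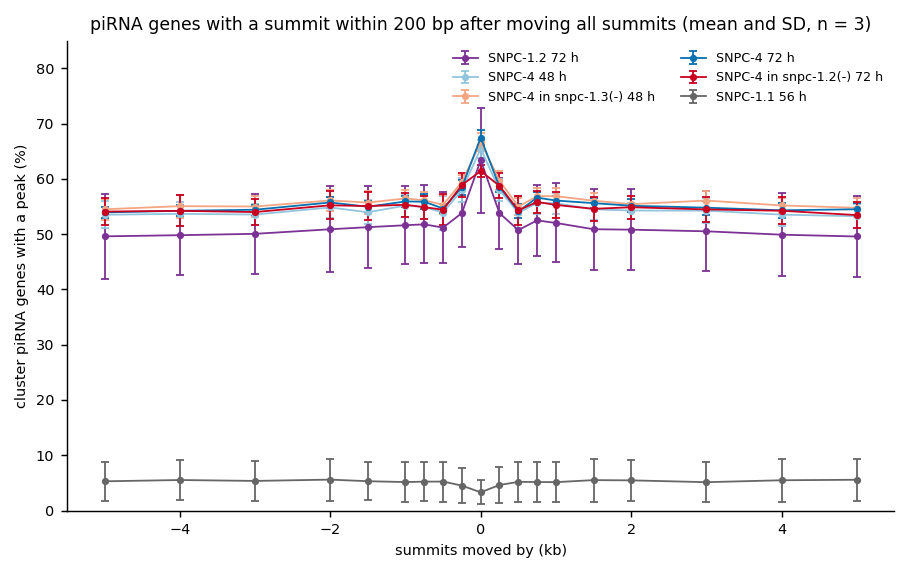
Percent of cluster piRNA genes with a peak (y axis) after moving every summit by the distance on the x axis (kb), mean ± SD of 3 libraries per group. The unmoved values are 67.5% for SNPC-4 at 72 h and 61.4% in worms without snpc-1.2, while both groups average 54.6% and 54.3% over summits moved by 2 to 5 kb.

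The change of SNPC-4 with age was compared between 48 h and 72 h in the same dataset. Its peaks lay at 61.7% ± 1.55 and 63.4% ± 1.22 of piRNA genes, 77.9% ± 0.589 and 81.0% ± 1.18 of snRNA genes, and the clusters held 42.5% ± 0.393 and 42.4% ± 0.678 of peaks. Exact two-sided permutation p was 0.2, 0.1 and 0.9 (adjusted 0.25, 0.136 and 0.931), where 0.1 is the smallest possible. The cluster share difference of −0.108 points turned to 0.0899 without 48 h replicate 1 and to 0.269 without 72 h replicate 3. In all libraries 295 piRNA genes were gained and 221 lost, against up to 55 in the other splits. This balance turned to 52 gained and 78 lost at 500 bp and to 23 and 73 by region overlap. Without N2 peaks it turned to 640 and 869, and there the piRNA percentage differed by −4.38 points. Replicate blocks, with their looser rule, gave 1069 gained and 794 lost. The gained count was 462 without SNPC-4 48 h replicate 1, and the lost count 333 without 48 h replicate 2, 341 without 72 h replicate 1 and 346 without 72 h replicate 3. The gained genes included 21ur-13132 (IV:14377241 to 14377261, fold 15.7) and 21ur-3619 (8.66), the lost ones 21ur-916 (IV:14445766 to 14445786, fold 33.0) and 21ur-6519 (10.9). The 1 snRNA gene gained was K09B11.15 (IV:13443395 to 13443496, fold 12.2), with 3 gained without 48 h replicate 3 and 2 without 72 h replicate 2. Gained microRNA genes were 5, including the neighbours mir-35, mir-36, mir-37 and mir-38 (4.60), microRNAs of the early embryo, and the lost ones were mir-75 (2.55) and let-7 (1.77), a regulator of late larval timing. Ribosomal protein genes with a SNPC-4 peak made up 19.7% ± 4.12 at 48 h and 54.7% ± 5.18 at 72 h, with 14 gained in all libraries, such as rpl-6 (2.70) and rpl-4 (2.55). Their N2 values were 10.3% ± 5.13 and 18.8% ± 12.1, and SNPC-4 minus N2 differed between the ages by 26.5 points (exact two-sided permutation p = 0.14, adjusted 0.445 over 35 tests). In worms without snpc-1.3, also at 48 h, SNPC-4 had a peak at 38.9% ± 22.1 of ribosomal protein genes, with libraries from 23.1% to 64.1%. The gained protein-coding genes numbered 309, including fbxa-215 (13.1) and hrpk-1 (8.79), and the lost ones 127, including col-138 (8.88), C52D10.3 (7.86) and irld-59 (7.79).

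SNPC-1.1 and SNPC-1.2 were compared as paralogues of the same subunit, although they also differed in tissue, age and dataset, which cannot be separated from the factor. SNPC-1.1 minus SNPC-1.2 was −56.1 points for piRNA genes, 37.4 points for snRNA genes and −69.7 points for the share of peaks in the clusters. Each had exact two-sided permutation p = 0.1, the smallest possible, with adjusted p = 0.136. All SNPC-1.1 libraries and no SNPC-1.2 library had a peak at 15 snRNA genes, including R07E5.16 (50.8), M163.13 (40.0) and F56H6.16 (37.7), at smy-6 (10.6), smy-4 (8.91) and sls-2.3 (73.2), and at yrn-1 (24.2). This count was 26 without SNPC-1.2 replicate 1 and 27 without SNPC-1.1 replicate 3. The reverse held for 4694 piRNA genes (7433 without SNPC-1.2 replicate 3), including 21ur-602 (27.3) and 21ur-6987 (26.4), for mir-78 (8.01), rps-18 (6.97) and dpy-4 (8.38), and for snpc-3.1 (7.68), which encodes another SNAPc subunit. A peak in all 6 libraries was found at 20 snRNA genes.

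The regions shared by the factors were compared last. Of 6924 SNPC-1.1 consensus regions 57.0% overlapped SNPC-4 regions at 48 h, against 9.53% after shifting, and 50.6% overlapped those at 72 h, against 8.91%. Of 2081 SNPC-1.2 regions 40.3% overlapped SNPC-4 at 72 h, against 16.3%, and 98.7% did when regions with N2 peaks were kept. Of the SNPC-1.1 regions 19.9% overlapped SNPC-1.2, against 6.95%, and 9.88% or 10.5% did without SNPC-1.2 replicate 1 or 2. SNPC-4 regions at 48 h overlapped those at 72 h for 66.6%, against 10.4%. Each age lost regions to its own N2 lists, 2592 of 8279 at 48 h and 3036 of 8273 at 72 h. A shared site removed at only 1 age counts as not overlapping, so the remainder cannot be called particular to an age. Each overlap had one-sided permutation p = 0.001, the smallest that 1000 shifts can give. Among factor genes, snpc-3.1 (IV:5484039 to 5486258, in the smaller cluster) had a peak in 3 of 3 SNPC-1.2 libraries and all SNPC-4 libraries, and in 1 of 3 N2 libraries at 48 h and at 72 h of dataset 2. The sex determination gene tra-1 had a peak in 3 of 3 libraries of each SNPC-4 group, 1 of 3 SNPC-1.2 and 1 of 3 SNPC-1.1 libraries. The snpc-1.1 gene had one in 3 of 3 libraries of each SNPC-4 group, 1 of 3 SNPC-1.2 and 2 of 3 SNPC-1.1 libraries. It also had one in 1 of 3 N2 libraries at each age of dataset 2. No library had a peak at snpc-4, snpc-1.3 or tofu-4.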

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

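The tests of tRNA background in N2 of both datasets, of shared copies and of matched fold, of the smaller cluster as a control, and of splits within replicate blocks were chosen only after the results were seen.

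Each of the values that follow was picked out because an effect differed between ages or nulls at exact two-sided permutation p under the threshold of 0.05. This held for 7 of 35 tests, and 0 stayed under it after Benjamini-Hochberg adjustment. SNPC-4 minus N2 for piRNA genes outside the clusters was 14.9 points at 48 h and 12.1 at 72 h, a difference of −2.79 (exact permutation p = 0.015, adjusted 0.131). For piRNA genes of the smaller cluster it was 67.6 and 64.9 points, a difference of −2.66 (exact permutation p = 0.025, adjusted 0.175). The effect of the null on SNPC-4 differed between snpc-1.2(-) at 72 h and snpc-1.3(-) at 48 h by −6.54 points for all piRNA genes and by −7.26 points for cluster piRNA genes (exact permutation p = 0.01 and adjusted 0.117 for both). For piRNA genes outside the clusters the nulls differed by 2.33 points (exact permutation p = 0.035, adjusted 0.194), and for miRNA genes by −2.44 points (exact permutation p = 0.045, adjusted 0.194). For piRNA genes of the larger cluster they differed by −8.98 points (exact permutation p = 0.01, adjusted 0.117). The nulls differ in the gene removed as well as in age, so these factors cannot be separated.

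The lower percent of larger-cluster piRNA genes with a SNPC-4 peak without snpc-1.2, a difference of −7.73 points, was weighed against technical explanations. The larger cluster held 4532 to 5051 summits in null libraries and 4771 to 5055 in controls. With all summits moved by −250 bp, cluster piRNA genes had a peak at 56.8% to 61.2% in the null and 56.9% to 59.3% in the control. By region overlap the piRNA difference turned direction, as given above. The −7.73 points therefore concern where summits lay near genes, and not fewer peaks in the larger cluster. Shorter lists are argued against, since with every list at 14538 peaks the difference was −8.17 points and all null libraries stayed below all controls. Lower enrichment over the whole library stays open. The bound first set against it, a null mean at or above the control in the smaller cluster, was met at 0.734 points but decides nothing, since that lies within the replicate spread (SD 1.5 and 1.22), and every null library lay below every control for miRNA genes (14.6% against 17.4%) and for protein-coding genes outside the clusters (13.1% against 15.3%), while piRNA genes outside the clusters lay above (16.1% against 13.7%). The genotype stays open as well.

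Cluster tRNA genes that kept a SNPC-1.2 peak in the SNPC-4 AID strain were weighed next. Antibody background of the kind seen in N2 of dataset 2 is argued against: there tRNA genes had peaks outside the clusters as well as inside (20.0% ± 11.0 and 28.5% ± 12.3 at 72 h, 29.8% ± 12.7 and 35.0% ± 17.6 at 48 h), with a largest gap of 9.93 points in any library, whole or cut to the length of an AID list, against at least 62.1 points in every AID library (71.5% ± 12.0 inside, 2.53% ± 2.34 outside). Background particular to dataset 1 and reads shared between tRNA copies stay open, although the bounds first set against them were met: the N2 lists of dataset 1 had a peak at 0% of these genes but hold only 2 to 16 peaks and could not reach the 63.4% of the lowest AID library, and the gap of 62.1 points is the pattern itself. These tRNA genes are among the strongest SNPC-1.2 sites, at a median percentile of 99.3 or more of fold among cluster summits, which is consistent with strong sites staying above the calling threshold, yet beside other cluster summits within 10% of their fold, summits at tRNA genes kept a peak more often by at least 32.1 points (these pairs covered 28 to 30 of 36 to 38 summits per library, and the tRNA side kept slightly higher median folds, 26.0 against 23.9, 23.2 against 21.8 and 19.6 against 18.1). What else, such as SNPC-1.2 in cells where the sun-1 promoter is not active, could leave these peaks was not tested.

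The low value of SNPC-1.2 replicate 3 in the smaller cluster was weighed against lower enrichment over the whole library. Replicates 1 and 2 shortened to the same number of peaks gave 2.31% and 10.2% there, against 4.15% in replicate 3, so lower enrichment may account for it. No biological explanation was tested.

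The counts of piRNA genes gained or lost come from 3 libraries against 3, whose 10 splits are too few for a share under 0.05. The real split was the only 1 of 10 to give as many genes lost in the AID strain (5021, highest other 2), lost or gained without snpc-1.3 (63 and 92, highest other 62), lost or gained without snpc-1.2 (592 and 248, highest other 56), and lost or gained between 48 h and 72 h (221 and 295, highest other 55). For genes gained in the AID strain the real count was 0 and all 10 splits gave as many, with 2 as the highest other. These splits ignore the replicate numbers, although same-numbered libraries correlated at 0.307 to 0.592 for the AID strain and SNPC-1.2 and at 0.462 to 0.847 for snpc-1.3(-) and its control. Within replicate blocks only 4 splits exist. There the AID strain had 9701 genes lost and 0 gained (highest other 2908), snpc-1.3(-) 472 and 612 (highest other 443), snpc-1.2(-) 1698 and 854 (highest other 598), and SNPC-4 at 72 h against 48 h 794 and 1069 (highest other 522).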

How the results depend on the processing

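The positional excess and the restrictions to the larger or smaller cluster were tests chosen only after the result was seen. For 43 results 675 alternative values were computed. Of those that left out 1 library, 302 kept their direction and side of the threshold or stayed near the main value, 18 moved, 3 reversed and 1 became weaker. Of the rest, 295 were unchanged in this sense, 34 moved, 19 reversed, 2 became stronger and 1 weaker. Designs of 3 against 3 cannot pass 0.05, so for these single comparisons the alternatives speak only of direction. Unknown depth limits every statement that a gene has no peak, above all in the AID strain, N2 of dataset 1 and SNPC-1.1 replicate 3. The motif results and their alternatives, and the division of snRNA genes by class, were not run. The cause was not tested for the values that follow, except that shortened lists hold fewer peaks by construction. Counts of lost or gained genes without 1 library or in replicate blocks can, by their rules, only equal or exceed the main count. With SNPC-1.1 against N2, the positional excess of piRNA genes was −1.88 points.

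For SNPC-1.2 in the AID strain, lost piRNA genes were 1736 with a 100 bp window, 10469 with 500 bp, 10632 by region overlap, 1055 at −log10 q of 10 or more, 1 with lists of the shortest length and 9701 in replicate blocks that pair the numbers, and 5021 to 7929 without 1 library. The difference in the cluster share was 3.52 points at fold 3 or more.

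For snpc-1.3(-), the piRNA difference was −0.488 points at 100 bp, −0.568 without N2 peaks and −0.239 as positional excess, and the snRNA difference −0.340 at 500 bp and at −log10 q of 10 or more. Without 1 library the snRNA difference was −0.340 to 0.680. Lost piRNA genes were 105 at 100 bp, 8 at 500 bp, 1 by region overlap, 32 without N2 peaks, 472 in replicate blocks and 101 to 168 without 1 library. Gained genes were 8 at 500 bp, 8 by region overlap, 47 without N2 peaks, 612 in replicate blocks and 147 to 214 without 1 library.

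For snpc-1.2(-), the piRNA difference was 0.462 points by region overlap, 2.56 without N2 peaks and 0.734 in the smaller cluster. Lost genes were 65 at 500 bp, 7 by region overlap, 982 at fold 3 or more, 296 without N2 peaks and 1698 in replicate blocks. Gained genes were 84 at 500 bp, 80 by region overlap, 536 at fold 3 or more, 854 in replicate blocks and 319 to 395 without 1 library. Over both nulls the piRNA difference was −3.54 points at 100 bp and −2.66 as positional excess (exact permutation p = 0.035 for both). It was 0.397 by region overlap, 0.995 without N2 peaks and 0.882 in the smaller cluster (exact permutation p = 0.305, 0.505 and 0.27). The snRNA difference was 0.510 at fold 3 or more. The cluster share differed by 2.57 points in replicate blocks (exact permutation p = 0.0625) and by 1.70 to 3.07 points without 1 library.

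For SNPC-4 at 72 h against 48 h, the piRNA difference was −0.0933 points at 500 bp, −0.861 by region overlap, −4.38 without N2 peaks and −2.59 in the smaller cluster. The snRNA difference was −1.36 without N2 peaks, and the cluster share −0.387 to 0.269 without 1 library. Lost genes were 78 at 500 bp, 73 by region overlap, 347 at fold 3 or more, 869 without N2 peaks, 794 in replicate blocks and 283 to 346 without 1 library. Gained genes were 52, 23, 445, 640 and 1069 under the same settings, and 388 to 462 without 1 library. In these blocks replicate numbers pair libraries, and over 24 pairs of same-numbered libraries the correlations were −0.521 to 0.847, with 14 above 0.1 and 12 highest with their own number.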

Other observations

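The lookups of age-dependent genes in other libraries were tests chosen only after the result was seen.

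The piRNA genes at which SNPC-4 gained or lost a peak between 48 h and 72 h were looked up in libraries that had not been used to pick them. These sets rest on summits within 200 bp. Counting by region overlap gave far fewer gained and lost genes, as given above. The sets therefore concern where summits lay more than whether a region was called. SNPC-1.2 at 72 h had a peak at 77.3% ± 12.0 of the 295 gained genes and at 34.4% ± 7.28 of the 221 lost genes. SNPC-4 in worms without snpc-1.2, also at 72 h, had a peak at 22.0% ± 2.06 of the gained and 68.5% ± 4.55 of the lost genes. SNPC-4 in worms without snpc-1.3 at 48 h had a peak at 40.8% ± 6.41 of the gained and 65.9% ± 6.91 of the lost genes. SNPC-1.1 at 56 h had a peak at 1.92% ± 1.04 and 0.905% of them.

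A hypothesis is that part of the change in SNPC-4 placement from larva to adult depends on SNPC-1.2. Sets picked by chance differences between libraries are argued against, since gained genes had a SNPC-1.2 peak more often than lost genes by at least 37.1 points in each of the 3 libraries. Part of this gap can come from location. Of the gained genes 254 lay in the larger and 30 in the smaller cluster, and of the lost genes 136 and 59. SNPC-1.2 had a peak at 68.9% of all piRNA genes in the larger cluster and 40.9% in the smaller. The share due to location was not tested. A second hypothesis was that SNPC-4 without snpc-1.2 keeps the 48 h pattern at 72 h. The gap it predicts, fewer gained than lost genes with a peak, was −43.2 points or lower in each null library. In the libraries of snpc-1.3(-) collected at 48 h it was −38.4 to −12.6 points. The sets were picked partly by the 72 h SNPC-4 libraries, the control of this null. Anything particular to that control could give such a gap, so the lookup cannot decide. The gap may also reflect culture or staging differences between strains, which were not tested. Neighbouring piRNA genes share summits, so the genes are not independent.

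The strongest sites also differed in kind between the factors. Of the 100 summits with the best q in each SNPC-1.2 library, 31 to 35 lay near tRNA genes and 95 to 99 in the clusters. In the SNPC-4 libraries of both ages 25 to 28 lay near snRNA genes and 14 near SL2 genes, and in SNPC-1.1 libraries 23 to 29 and 15. The best-ranked SNPC-1.2 consensus region spanned 160595 bp (IV:14257345 to 14417939). Among SNPC-1.1 consensus regions, which exclude those with an N2 peak, the best-ranked covered rpr-1, at a median rank of 15 in the whole lists.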
